A study of Danio rerio with 10 samples.

How the data were processed

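RNA was measured by CEL-seq, a 3′ tag method, in 10 libraries of sorted zebrafish cells of the AB strain, 5 from embryos with the caged tracer alone (control) and 5 from embryos with the tracer and the caged *spadetail* morpholino (spt_cMO). Per the labels' protocols, cells were lysed as they were sorted, RNA integrity numbers were between 8.1 and 9.9, and the barcoded libraries were combined before sequencing. The labels mention no molecular identifiers, so counts are treated as reads, and intervals and floors from them cover counting error only.

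The authors deposited a table of raw read counts per RefSeq transcript record. Per the series' design text, reads were aligned to the zebrafish assembly Zv8 with custom CEL-seq scripts in Galaxy; the aligner, the counter, its use of strand and their versions are not stated. The authors also deposited their comparison of the groups, with a log2 fold change, a mean log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value per record; per the submitters' processing notes it was made with edgeR, with no version given. That table holds no values per library. It listed 6923 records, exactly those with a CPM above 2 in at least 5 libraries, and its log2 fold changes were met within 0.0034 by an edgeR likelihood ratio model with group and replicate number, against 0.48 by a model with group alone. Across the genes tested in both, which are not independent replicates, its log2 fold changes and those computed here had a Pearson r of 0.987.

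The count table held 14720 records, of which 1712 were at 0 in every library. Symbols came from a RefSeq gene table of the assembly GRCz12tu, used for names only, in which 13986 records matched; records without a symbol took between 1.4% and 1.62% of each library's counts and stayed in the tests. No genome of the authors' build was used here, so no coordinates are given, and a check of GC content or transcript length was not made. No pair of libraries had the same counts (chi-square per degree of freedom between 7.44 and 23.7).

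Counts were analysed in R 4.3.3 with edgeR 4.0.16. Records were kept by filterByExpr (minimum count 10, minimum total 15, minimum proportion 0.7), which left 6570, of which 6379 had a symbol. Library sizes were scaled by TMM, and the groups were compared with the robust quasi-likelihood test of glmQLFit and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment at 0.05. CPM values are TMM-scaled, given as mean ± SD over 5 libraries, and fold changes are spt_cMO over control with the standard error taken from the F statistic. On simulated counts for 6570 genes with the depths and means of this comparison, the test recovered 40% of genes changed 1.5-fold, 76% of those changed 2-fold and 96% of those changed 3-fold or 4-fold, with 10 unchanged genes among 170 calls.

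A total of 23 gene lists were fixed before the data were examined, and 22 were tested, since no record matched the mitochondrial genome. They were the hox genes, ribosomal proteins, T-box factors, presomitic and paraxial mesoderm, muscle progenitors, cdx and caudal regulators, posterior progenitors, intermediate and lateral mesoderm with blood and endothelium, notochord and axial mesoderm, endoderm, neural ectoderm, epidermis and enveloping layer, yolk syncytial layer, primordial germ cells, p53 response, the Wnt, FGF, Notch, retinoic acid and BMP and Nodal pathways, adhesion, matrix and migration, and cell cycle. Each was compared with all other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with a correlation estimated per list. By camera 6 lists passed, and with an estimated correlation none did. With fry, which tests whether a list's genes move one way on balance, 5 passed. An exact permutation of each list's mean per library over the 252 assignments of the libraries was added after the data were seen, and 4 passed. On simulated data camera called the 1 shifted list and none of 20 unchanged lists. Genes were simulated independently of each other, so this does not measure false calls in lists whose genes move together. The hox list, for example, had an estimated correlation of 0.17.

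Hox paralog classes, totals, records detected and the share of the 10 most counted records were compared by 2-sided exact permutation tests over 252 assignments, with Benjamini-Hochberg adjustment within each family. The smallest p of that test is 0.00794, and that of exact sign flips over 5 pairs 0.0625.

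The labels give both groups the replicate numbers 1 to 5 and do not say what a number shares. Over all 6570 tested genes, the deviations of same-numbered libraries from their group means correlated at 0.135, 0.251, 0.119, 0.203 and 0.147 for numbers 1 to 5, all above the 0.1 set for calling the numbers paired. Control replicate 3 correlated slightly better with a library of another number (0.144). Over 2955 genes with a mean log2 CPM above 5 the values were 0.063, 0.26, 0.203, 0.263 and 0.132, and control replicates 1, 3 and 4 correlated better with a library of another number (0.1, 0.23 and 0.293), so the pairing is uncertain. The comparison without the block is given first and the blocked value beside it where it changes a call or moves a count by over 1.5 times.

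Named genes followed a rule fixed before the data were examined: *tbx16*; the 10 highest and 10 lowest called genes by log2 fold change among those with at least the median abundance of tested genes (25.6 CPM); the 3 with the smallest p in each direction among the rest; and up to 4 called members of each list with the smallest p, or the 1 member with the smallest p where none was called. It gave 57 genes. Others are marked where named.

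The alternatives were other size factors (RLE and upper quartile), no filter and a filter at a mean of 20 CPM, no robust estimation, the replicate block, DESeq2 1.42.0, edgeR's exact test, limma-voom with quality weights, thresholds of 0.1 and 0.01, a prior count of 0.5, detection at 5 counts, and leaving out each library and each replicate number. Added after the data were seen were the authors' model, thinning every library to the smallest total, the estimated correlation with the block, the exact permutation of list means (also after thinning), and the hox classes on the same genes. Other omissions ran the filter again.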

Results

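Zebrafish embryos carried either a caged fluorescein-dextran tracer alone (control) or the tracer together with a caged morpholino against *spadetail* (spt_cMO). A caged morpholino is an antisense oligonucleotide that is inactive until light releases it, and *spadetail* is the older name of *tbx16*, a T-box transcription factor of mesoderm progenitors. Ventral somite progenitors were uncaged with 360 nm light through a diaphragm of 100 µm at 6 hours post-fertilization (hpf), and fluorescein-positive cells were sorted at 9 hpf, in late gastrulation. RNA was counted by CEL-seq, which reads a tag near the 3′ end of each transcript. Each group held 5 libraries, numbered 1 to 5. Control libraries 1 to 5 held 4033029, 7968446, 3365785, 4706124 and 7368657 counts, and spt_cMO libraries 1 to 5 held 9374914, 2036973, 2779275, 3807655 and 2460395.

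Library depth and complexity gave no detectable group difference. Totals averaged 5488408 counts ± 2056791 (SD, n = 5) in control and 4091842 ± 3024837 (SD, n = 5) in spt_cMO (exact permutation p = 0.389, 2-sided). Without spt_cMO replicate 1, the deepest library, the difference was -2717334 counts (exact permutation p = 0.0476). Records with at least 1 count numbered 10485 ± 628 in control and 10092 ± 711 in spt_cMO (exact permutation p = 0.357), and the 10 most counted records took 13.9% ± 0.767 and 14.1% ± 0.376 of the counts (exact permutation p = 0.667). The heat shock gene *hspb1* was the most counted gene, with 2.63% of all counts, followed by the actin gene *actb2* with 2.34%, both named outside the rule. Over the 3 measures the adjusted p was 0.583 or higher. A count of 3 corresponded to between 0.32 CPM (read counts scaled to library size) in the deepest library and 1.47 CPM in the shallowest, a limit that covers counting error only. Of the first principal component of all tested genes, spt_cMO replicate 2 took the most extreme value, -0.83, and the other 9 libraries lay between -0.17 and 0.34.

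The targeted gene was read first in every library. *tbx16* (RefSeq record NM_131058) was counted at 386 CPM ± 45.1 (SD, n = 5) in control and at 526 CPM ± 100.3 (SD, n = 5) in spt_cMO, a log2 fold change of 0.45 (SE 0.13). All 5 spt_cMO libraries lay above the control mean and 4 of them above every control library. The difference did not pass edgeR's quasi-likelihood test (adjusted p = 0.0897). With the replicate number as a block, the log2 fold change was 0.43 and it passed (adjusted p = 0.0172), and without spt_cMO replicate 4 it was 0.54 (adjusted p = 0.0239). The adjusted p ranged from 0.0027 to 0.41 over the alternatives. A morpholino blocks translation or splicing and need not lower its target's transcript, so 3′ tags of *tbx16* are a weak check of the labels.

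The comparison of the groups asked which transcripts of early somite progenitors differ with the caged *spadetail* morpholino. Control embryos carried no morpholino, so loss of *spadetail* cannot be told apart from other effects of a morpholino. The transcript of *msgn1*, a basic helix-loop-helix factor of the presomitic mesoderm, fell from 5838 CPM ± 774 to 2029 CPM ± 632 (SD, n = 5 each), 2.88-fold lower, with a log2 fold change of -1.53 (SE 0.19). The chemokine transcript *cxcl12a* fell from 1641 CPM ± 114 to 667 CPM ± 156 (log2 fold change -1.30, SE 0.14), and *tbx16l*, a T-box gene related to *tbx16*, from 783 CPM ± 67.0 to 442 CPM ± 66.4 (log2 fold change -0.83, SE 0.11). In the other direction, *cyp26a1*, which encodes an enzyme that degrades retinoic acid, rose from 669 CPM ± 64.2 to 1146 CPM ± 133 (log2 fold change 0.78, SE 0.10). The adhesion molecule gene *mcamb* rose from 12.5 CPM ± 2.93 to 44.6 CPM ± 6.48, 3.55-fold higher, and the sphingosine-1-phosphate receptor gene *s1pr1* from 19.6 CPM ± 2.05 to 51.2 CPM ± 6.32, 2.62-fold higher. In each of these 6 genes all 5 spt_cMO libraries lay outside the range of all 5 control libraries, and the adjusted p ran from 2.72e-06 for *mcamb* to 0.000467 for *msgn1* (edgeR's quasi-likelihood test).

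Among 6570 tested transcript records, 117 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 53 of them higher and 64 lower in spt_cMO. With the replicate number as a block 88 were higher and 93 lower, and all 117 were among them. The groups did not overlap in 201 of the 6570 tested records (3.06%), where chance gives 0.794%. Of the 117, 101 did not overlap and 70 had an absolute log2 fold change under 1. An unadjusted p under 0.05 was reached by 620 records. In the authors' own deposited comparison, which listed 6923 records, 127 were higher and 121 lower; it included all 117, none with the opposite sign, and called another 122 of the records tested here.

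**Figure D1:**
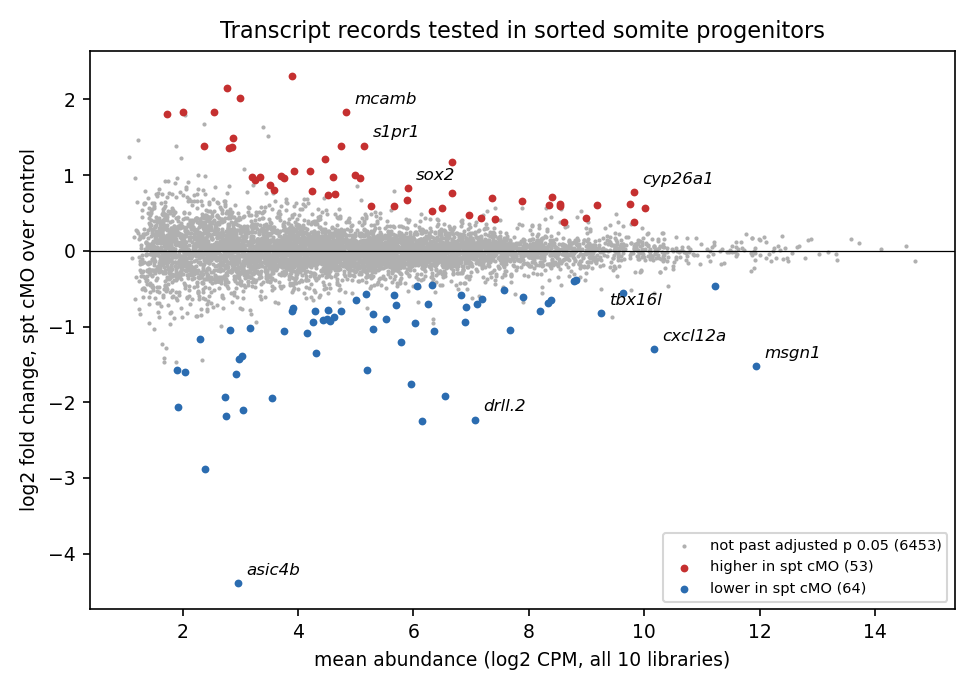
Log2 fold change of spt_cMO over control against mean abundance in log2 CPM for the 6570 tested transcript records, 1 point each; 53 higher records are red, 64 lower records blue and the other 6453 grey. The abundant genes *msgn1* and *cxcl12a* lie below 0, and *cyp26a1* lies above it.

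Among the more abundant tested genes, the lower end was led by the protocadherin gene *pcdh10b*, with a log2 fold change of -2.25 (SE 0.23). It was followed by *drll.2* at -2.23 (SE 0.21), *drll.1* at -1.91 (SE 0.12), the cytochrome P450 gene *cyp27c1* at -1.76 (SE 0.19) and *tpd52l2a* at -1.57 (SE 0.23). The cytoskeletal genes *septin9a* and *actc1a* fell with log2 fold changes of -1.06 (SE 0.15) and -1.04 (SE 0.14), and *arl4aa* with -1.20 (SE 0.25). Of the less abundant genes, the acid-sensing ion channel gene *asic4b* fell from 14.6 CPM ± 2.2 to 0.925 CPM ± 0.792, a level within the 0.32 to 1.47 CPM that 3 counts make up in the libraries. *hhip*, which encodes a hedgehog-binding protein, fell 2.54-fold, from 28.4 CPM ± 1.90 to 11.4 CPM ± 1.79. The copies *drll.1* and *drll.2* are closely related, and counting could have split reads between them, so their single values are uncertain. Without control replicate 4 the call of *arl4aa* was lost (adjusted p = 0.0866), as it was without any of 5 other libraries; the other 9 genes of this paragraph kept theirs without each library.

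Among the more abundant tested genes, the higher end was led, after *mcamb* and *s1pr1*, by the growth factor gene *bmp2a*, which rose from 14.8 CPM ± 4.51 to 39.1 CPM ± 4.39 (log2 fold change 1.39, SE 0.18). The cytoskeletal gene *tagln3b* rose with a log2 fold change of 1.17 (SE 0.11), the metalloprotease gene *adam8a* with 1.00 (SE 0.13), the sodium pump gene *atp1a1b* with 0.96 (SE 0.17) and *prkar2aa*, a regulatory subunit of protein kinase A, with 0.77 (SE 0.11). Of the less abundant genes, *b3gnt7l* rose from 5.21 CPM ± 1.63 to 24.6 CPM ± 7.69 and *hivep2a* from 2.46 CPM ± 0.749 to 11.1 CPM ± 1.83. These 7 genes kept their calls without each single library.

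**Figure D2:**
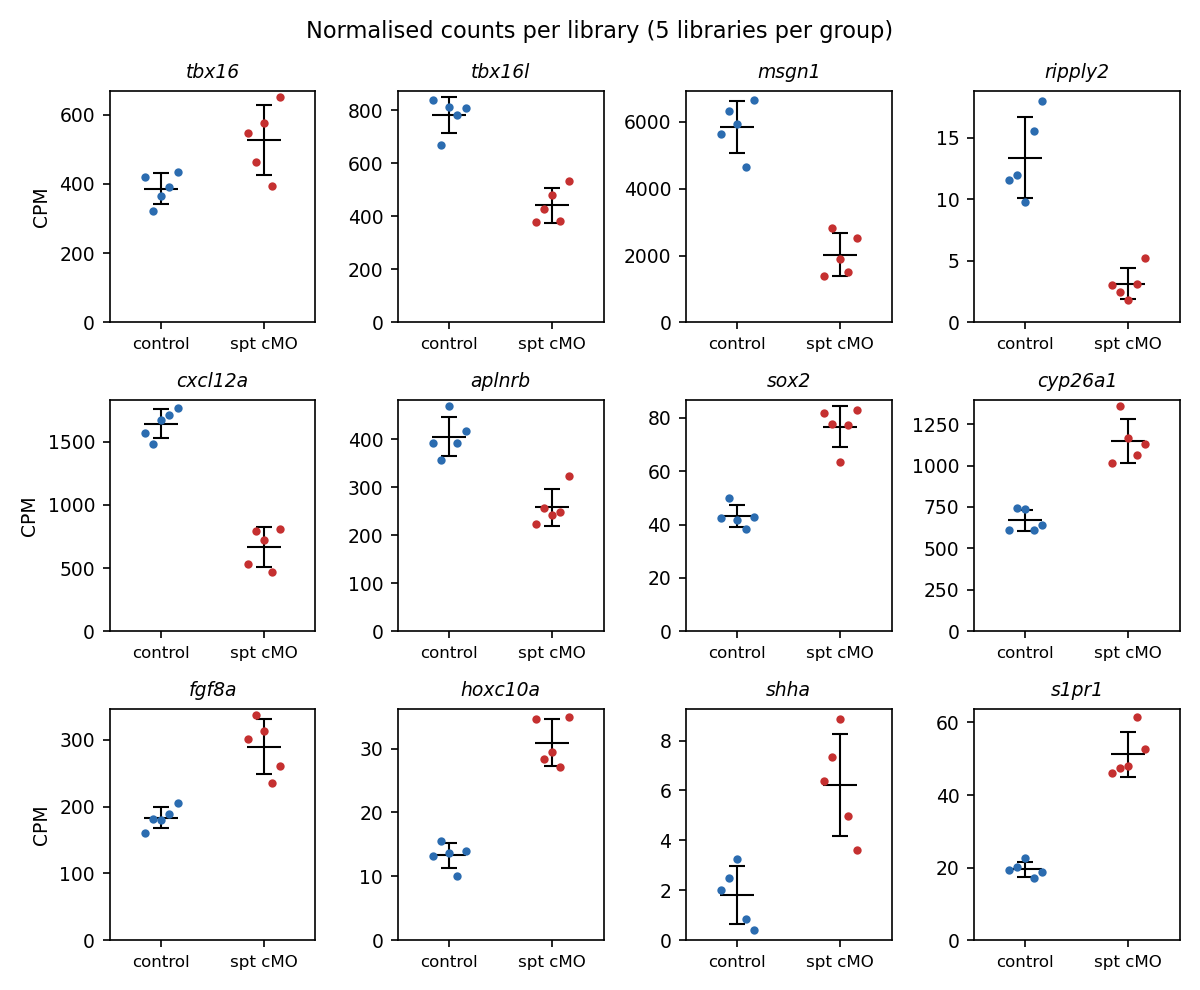
CPM per library for 12 genes in control (blue) and spt_cMO (red), 5 libraries each, with the mean as a horizontal line and the SD as bars. *msgn1*, *tbx16l*, *ripply2*, *cxcl12a* and *aplnrb* are lower in every spt_cMO library than in any control library, *tbx16* overlaps between the groups, and the other 6 genes are higher in every spt_cMO library.

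Genes of the presomitic and paraxial mesoderm, the tissue that forms the somites, moved mainly down. Of 31 tested members 10 fell, 3 rose and 18 did not pass; adjusted over the list alone, 13 were lower and 5 higher, and with the replicate number as a block 12 were lower and 5 higher. The segmentation genes *ripply2*, a corepressor of segment borders, and *her11* fell with log2 fold changes of -2.10 (SE 0.25) and -1.93 (SE 0.27), beside *msgn1* and *tbx16l*. The oscillating gene *her1* fell from 288 CPM ± 42.6 to 188 CPM ± 47.7. The other 5 that fell were *tcf15* (-1.94), *pcdh8* (-2.07), *foxc1a* (-0.96), *foxc1b* (-0.92) and *dact2* (-0.71), log2 fold changes of genes chosen after their values were seen. Against the list, *fgf8a* rose from 183 CPM ± 16.01 to 289 CPM ± 41.2, the Notch modifier *lfng* from 257 CPM ± 48.2 to 419 CPM ± 63.8 and the Notch target *her15.2*, 1 of several related copies, from 833 CPM ± 85.6 to 1231 CPM ± 200.4. The list as a whole lay 0.46 log2 units below other genes (difference -0.46, camera adjusted p = 2.76e-05), with adjusted p = 0.141 with an estimated correlation. In an exact permutation of the list's mean per library, chosen after the data were seen, the difference was -0.46 (p = 0.00794, the smallest that 5 against 5 libraries can give; adjusted p = 0.0437 over 22 lists). The primordial germ cell list also lay lower by camera, with a difference of -0.34, but none of its 8 genes passed and the adjusted p was 0.23 with an estimated correlation and 0.175 in the exact permutation. Without spt_cMO replicate 4 the call of *her1* was lost (adjusted p = 0.132), as it was without any of 7 other libraries. Those fits had no block. With the replicate block and all libraries, the adjusted p of *her1* was 0.00098.

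The T-box and muscle lists held few tested genes. Of 4 T-box factors, the target *tbx16* among them, *tbx16l* fell. *tbxta*, the brachyury gene of posterior mesoderm, rose from 338 CPM ± 21.3 to 439 CPM ± 44.2. Both adjusted over the list alone and with the block, 2 were higher (*tbx16* and *tbxta*) and 1 lower. The T-box list did not pass (camera adjusted p = 0.542). Of 6 muscle progenitor genes *six4a*, a homeobox gene, fell from 39.1 CPM ± 3.31 to 24.9 CPM ± 1.18 and 5 did not pass (camera adjusted p = 0.542); adjusted over the list alone, 1 was higher and 1 lower. This list's median log2 fold change was 0.21, and its 5 other members were positive. Without spt_cMO replicate 1 the call of *tbxta* was lost (adjusted p = 0.148), as it was without any of 8 other libraries.

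The hox genes, which pattern the body axis, were higher in spt_cMO as a group. Of 26 tested genes 4 rose, none fell and 22 did not pass, and 22 had a positive log2 fold change. *hoxc10a* rose from 13.3 CPM ± 2.03 to 30.9 CPM ± 3.64 (log2 fold change 1.22, SE 0.14) and *hoxb10a* from 45.6 CPM ± 9.14 to 73.5 CPM ± 6.90 (log2 fold change 0.68, SE 0.13). *hoxd10a* rose with a log2 fold change of 0.87 (SE 0.22) and *hoxc3a* with 0.43 (SE 0.10). With the replicate number as a block 8 were higher, and adjusted over the list alone 9 were higher and none lower, but this list was taken from what is known of the study of these samples and is not independent evidence. The list lay 0.36 log2 units above other genes (camera adjusted p = 5.49e-08), with adjusted p = 0.141 with an estimated correlation. Its exact permutation over libraries gave a difference of 0.35 (p = 0.00794, adjusted p = 0.0437). The epidermis list also lay higher by camera, with a difference of 0.13, but none of its 28 genes passed and the adjusted p was 0.636 with an estimated correlation and 0.742 in the exact permutation. The calls of *hoxc3a* and *hoxd10a* were lost without single libraries, with adjusted p up to 0.087 without control replicate 4 and 0.132 without control replicate 5.

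Split by paralog group, from anterior to posterior, the posterior hox genes differed most. The 9 genes of groups 9 to 13 averaged 4.18 log2 CPM ± 0.25 (SD, n = 5) in control and 4.75 ± 0.14 in spt_cMO, a difference of 0.56 (exact permutation p = 0.00794, adjusted p = 0.0238). The 8 genes of groups 1 to 4 averaged 4.22 ± 0.16 and 4.49 ± 0.08, a difference of 0.28 (exact permutation p = 0.0159, adjusted p = 0.0238). The 9 genes of groups 5 to 8 averaged 4.77 ± 0.22 and 4.97 ± 0.11, a difference of 0.20 that did not pass (exact permutation p = 0.111). The difference of groups 9 to 13 exceeded that of groups 1 to 4 by 0.28 and that of groups 5 to 8 by 0.36 (exact permutation p = 0.00794 each, adjusted p = 0.00794). As 5 matched pairs, groups 1 to 4 and 9 to 13 were higher in 5 of 5 and groups 5 to 8 in 4 of 5, and exact sign flips gave p = 0.0625, 0.0625 and 0.125, where 0.0625 is the smallest that 5 pairs allow. On the same genes, the call of groups 1 to 4 was lost without spt_cMO replicate 2, 3 or 4 (adjusted p = 0.0714 each), groups 5 to 8 passed only without control replicate 3 (difference 0.26, adjusted p = 0.0317), and groups 9 to 13 passed without each library (0.47 to 0.63). With the filter run again after each omission, which changed the hox genes compared, groups 1 to 4 lost the call in 7 of 10 fits (adjusted p up to 0.119) and groups 5 to 8 passed in 5 (differences of 0.29 to 0.35).

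**Figure D3:**
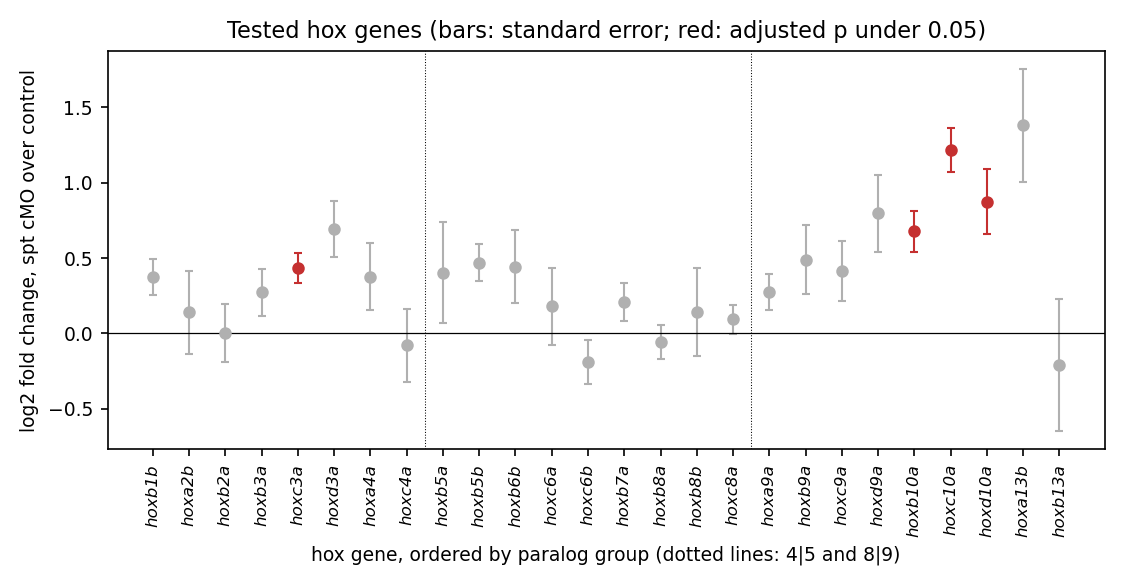
Log2 fold change of spt_cMO over control, with its standard error, for the 26 tested hox genes in order of paralog group; red points passed an adjusted p of 0.05. The 4 red points are *hoxc3a*, *hoxb10a*, *hoxc10a* and *hoxd10a*, and 3 of them lie in groups 9 to 13.

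Genes of posterior progenitors, the cells that feed the growing body axis, moved in both directions. Of 18 tested members *cyp26a1*, *fgf8a*, *sox2* and *tbxta* rose, *fgf24* and *her1* fell and 12 did not pass; adjusted over the list alone, 5 were higher and 3 lower. *sox2*, a SOX factor of neural and progenitor cells, rose from 43.1 CPM ± 4.13 to 76.7 CPM ± 7.77 (log2 fold change 0.83, SE 0.11), and the growth factor gene *fgf24* fell from 24.9 CPM ± 4.86 to 14.6 CPM ± 3.29. The list did not pass (camera adjusted p = 0.139); it did by fry (adjusted p = 0.0211), and its exact permutation over libraries gave a difference of 0.08 (p = 0.0238, adjusted p = 0.105). Among 11 cdx and caudal regulators *meis1b*, a hox cofactor, fell from 34.1 CPM ± 8.79 to 19.8 CPM ± 4.09 and 10 did not pass (camera adjusted p = 0.434); adjusted over the list alone, 2 were higher and 2 lower. The calls of *fgf24* and *meis1b* were lost without single libraries, with adjusted p up to 0.107 without spt_cMO replicate 1 and 0.105 without spt_cMO replicate 4, and those of *tbxta* and *her1* as given with their lists.

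Notch pathway genes were shifted upward as a set. Of 29 tested members *lfng* and *her15.2* rose, *notch2* and *her1* fell and 25 did not pass; adjusted over the list alone, 5 were higher and 2 lower, and with the block 4 and 2. The receptor gene *notch2* fell from 29.6 CPM ± 3.61 to 15.96 CPM ± 2.84 (log2 fold change -0.90, SE 0.15). The set lay 0.18 log2 units above other genes (camera adjusted p = 0.00943), with adjusted p = 0.141 with an estimated correlation. That estimate was -0.011, below the preset 0.01, with a camera p of 0.00657 before adjustment. The set's exact permutation over libraries gave a difference of 0.17 (p = 0.00794, adjusted p = 0.0437), and 15 of the 29 tested members also stood in another list. With all libraries thinned to the smallest total the camera call was lost (difference 0.15, adjusted p = 0.0743), while the exact permutation still passed (difference 0.17, adjusted p = 0.0437).

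Genes of adhesion, matrix and migration included some of the largest decreases. Of 35 tested members 6 fell, 1 rose and 28 did not pass; adjusted over the list alone, 8 were lower and 2 higher, and with the block 7 and 2. Beside *cxcl12a*, the apelin receptor genes *aplnra* and *aplnrb* fell with log2 fold changes of -0.75 (SE 0.10) and -0.65 (SE 0.11), and *has2*, which encodes a hyaluronan synthase, fell from 11.7 CPM ± 2.16 to 4.57 CPM ± 0.794. *pcdh8* and the fibronectin gene *fn1b* (-0.69) also fell and the planar polarity gene *prickle1b* rose (log2 fold change 0.70), which were named after their values were seen. The list lay 0.20 log2 units below other genes (difference -0.20, camera adjusted p = 0.0306), with adjusted p = 0.141 with an estimated correlation. That estimate was -0.0006, below the preset 0.01, with a camera p of 0.0136 before adjustment. The list's exact permutation over libraries gave -0.21 (p = 0.00794, adjusted p = 0.0437). Its mean log2 fold change was -0.22 but its median -0.0055. The camera call was lost without control replicate 2 (adjusted p = 0.0924), 3 (0.126), 4 (0.0871) or 5 (0.0503) and without spt_cMO replicate 1 (0.0538) or 3 (0.065). It was also lost without a filter on low counts (difference -0.11, adjusted p = 0.206) and after thinning (difference -0.11, adjusted p = 0.183), where the exact permutation still passed (difference -0.16, adjusted p = 0.0437).

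Of 23 tested Wnt pathway genes *sfrp1a*, *tcf7l1a* and *fzd10* fell, *tbxta* rose and 19 did not pass; adjusted over the list alone, 5 were lower and 2 higher, and with the block 3 and 2. The secreted Wnt antagonist *sfrp1a* fell from 52.6 CPM ± 8.66 to 26.0 CPM ± 4.75, the transcription factor *tcf7l1a* with a log2 fold change of -0.88 (SE 0.16) and the receptor *fzd10* with -0.93 (SE 0.17). After thinning the call of *fzd10* was lost (log2 fold change -0.86, adjusted p = 0.101). The list did not pass (camera adjusted p = 0.375). Of 15 FGF pathway genes *fgf8a* rose, *fgf24* fell and 13 did not pass (camera adjusted p = 0.219), with the same counts adjusted over the list alone. Of 13 retinoic acid pathway genes *cyp26a1* rose and 12 did not pass; adjusted over the list alone, 1 was higher and 2 lower, and with the block 1 and 1. That list did not pass (camera adjusted p = 0.542, direction up), while its median was -0.02 and its mean -0.03. Of 27 BMP and Nodal pathway genes the Nodal antagonist *lft1* fell from 60.0 CPM ± 17.2 to 32.4 CPM ± 6.78 and 26 did not pass (camera adjusted p = 0.237); adjusted over the list alone, 6 were higher and 2 lower, and with the block 2 and 1. The list passed without control replicate 3 (adjusted p = 0.0476). The call of *lft1* was lost without single libraries, with an adjusted p up to 0.126 without spt_cMO replicate 1.

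Markers of other cell types were read as a measure of what the sorts held. Among 16 notochord and axial mesoderm genes *shha*, *foxd3* and *tbxta* rose, *arl4aa* and *lft1* fell and 11 did not pass (camera adjusted p = 0.237), with 3 higher and 2 lower adjusted over the list alone. *foxd3* rose from 2.49 CPM ± 0.835 to 9.21 CPM ± 3.49 and the hedgehog ligand gene *shha* from 1.81 CPM ± 1.17 to 6.23 CPM ± 2.04, both low levels. Among 29 neural ectoderm genes *sox2* rose and 28 did not pass, with the same count adjusted over the list alone (camera adjusted p = 0.0658, and 0.0333 with the replicate number as a block). With an estimated correlation the adjusted p was 0.636, and 0.565 with the block, and in the exact permutation over libraries it was 0.736. By camera that list passed without control replicate 2 (adjusted p = 0.03) or 3 (0.0181) or spt_cMO replicate 4 (0.00771). Among 11 genes of the intermediate and lateral mesoderm, blood and endothelium *osr1* fell from 92.5 CPM ± 9.77 to 67.5 CPM ± 7.30 and 10 did not pass (camera adjusted p = 0.102); 2 were lower both adjusted over the list alone and with the block, and the list passed without control replicate 1 (adjusted p = 0.0165). Of 12 endoderm genes *fgf24* fell and 11 did not pass (camera adjusted p = 0.393), with the same count adjusted over the list alone. The call of *shha* was lost without control replicate 4 or spt_cMO replicate 1 or 3 (adjusted p = 0.0524, 0.0673 and 0.0621), and that of *osr1* without any of 7 libraries (adjusted p up to 0.132, without control replicate 5).

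No single gene of the epidermis or germ cell lists passed, over all genes or adjusted over the list alone, although both lists did by camera. The 28 epidermis and enveloping layer genes lay 0.13 log2 units above other genes (camera adjusted p = 0.0486), with adjusted p = 0.636 with an estimated correlation; *klf2a*, with the smallest p, was at 72.8 CPM ± 12.3 and 97.4 CPM ± 9.60 (adjusted p = 0.116). The 8 primordial germ cell genes had a difference of -0.34 from other genes (camera adjusted p = 0.0306), with adjusted p = 0.23 with an estimated correlation; *cxcr4b* was at 12.9 CPM ± 3.56 and 9.35 CPM ± 2.09 (adjusted p = 0.625). In the exact permutation over libraries the adjusted p was 0.742 for the epidermis and 0.175 for the germ cells. The epidermis call was lost without control replicate 4 (adjusted p = 0.242) or spt_cMO replicate 2 (0.513) or 4 (0.0983), without a filter on low counts (0.206), with RLE size factors (0.0512) and with a prior count of 0.5 (0.0513), and the germ cell call without control replicate 4 (0.0867) or spt_cMO replicate 2 (0.143) or 5 (0.0684) and after thinning (0.0743). Within spt_cMO, replicate 2 had the highest mean of both the epidermis list (0.53 log2 CPM above the mean of all libraries) and the notochord list (0.58). With the replicate number as a block *klf2a* passed (log2 fold change 0.43, adjusted p = 0.0249).

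**Figure D4:**
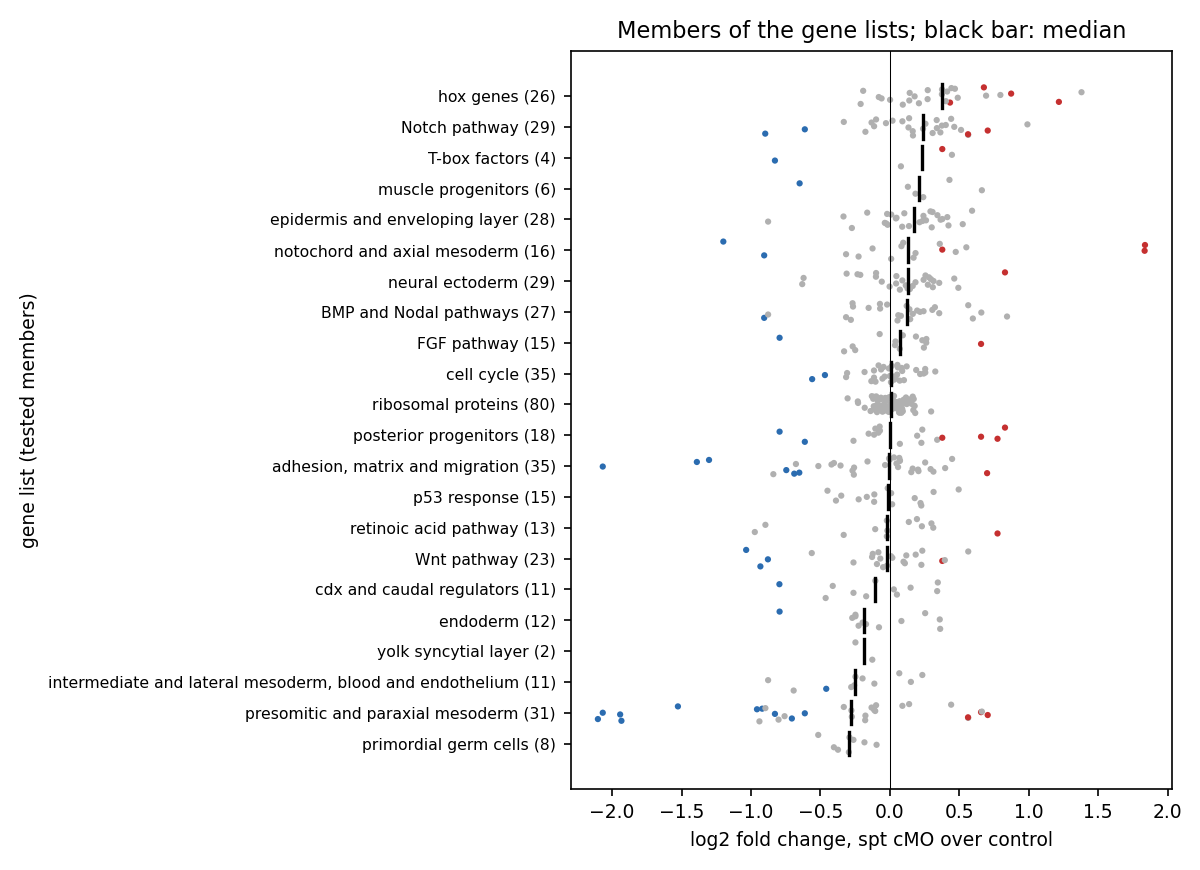
Log2 fold change of spt_cMO over control for every tested member of the 22 tested gene lists, with the number of tested members in brackets and the list median as a black bar; members past an adjusted p of 0.05 are red where higher and blue where lower. The hox median is 0.38 and the presomitic and paraxial mesoderm median -0.28.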

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

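The tests for cells of the notochord, of neural tissue, of caudal tissue and for fewer paraxial cells were chosen after the results were seen. So was the thinning of libraries for the lists and hox genes, although what each thinning would show was written before it was run.

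In 8 of 170 groups of 5 libraries a single library lay far from the other 4, where chance gives about 1 in 20 groups, or 8.5. The *adam8a* level in spt_cMO replicate 3 was 34.7 CPM, below the other 4 at 42.6 to 45.4 CPM. The *sox2* level in the same library was 63.5 CPM, below the others at 77.5 to 82.9 CPM. In spt_cMO replicate 5 *her11* was at 5.23 CPM, above the others at 1.96 to 2.65 CPM. In spt_cMO replicate 2 *sfrp1a* was at 34.3 CPM, above the others at 22.7 to 25.8 CPM. In control replicate 4 the ribosomal gene *rpl11* was at 731 CPM, below the others at 913 to 957 CPM. The mean of hox paralog groups 5 to 8 was 5.16 log2 CPM in spt_cMO replicate 2, above the others at 4.89 to 4.96. The total of spt_cMO replicate 1 was 9374914 counts, above the other spt_cMO libraries at 2036973 to 3807655. The presomitic and paraxial mesoderm list had a mean of 0.37 log2 CPM in control replicate 5, relative to the mean of all libraries, above the other controls at 0.17 to 0.22.

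The presomitic and paraxial mesoderm list lay lower in spt_cMO by camera (adjusted p = 0.141 with an estimated correlation), with 10 of 31 genes lower, 3 higher and 18 not past the test. Shallower spt_cMO libraries are argued against, because with every library thinned to 2036973 counts the list still lay below other genes (difference -0.40) and its mean per library still differed by -0.42 (exact permutation p = 0.00794, adjusted p = 0.0437). Fewer paraxial mesoderm cells in the sorts cannot be told apart from a change within the cells. If all other cell types filled the gap in proportion, their lists would rise alike. The epidermis list moved 0.33 log2 units more than the lateral mesoderm list (exact permutation p = 0.0873). Cells of a single other type could fill the gap instead, so this contrast cannot decide. Of the 6 other lists, germ cells (-0.35, exact permutation p = 0.0476, adjusted p = 0.286), lateral mesoderm (-0.20) and endoderm (-0.09) were lower and notochord (0.21), epidermis (0.12) and neural tissue (0.11) higher, none past an adjusted p of 0.05. The injected morpholino, the design's own difference, stays open as a biological cause.

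The hox list lay higher in spt_cMO by camera (adjusted p = 0.141 with an estimated correlation), with 4 of 26 genes higher and 22 not past the test, and the mean of paralog groups 9 to 13 differed most. Thinning argues against depth, since groups 9 to 13 still differed by 0.66, or by 0.54 on the same genes (exact permutation p = 0.00794 each). A larger share of caudal cells cannot be told apart from a change within the cells: the median log2 fold change of the 18 tested posterior progenitor genes was 0.00055 where the hox median was 0.38, but 9 were positive and 9 negative with an SD of 0.43, more than that gap, and their mean per library was 0.08 higher (exact permutation p = 0.0238, adjusted p = 0.105). All 18 also stand in another list, and an effect of the morpholino on hox transcription stays open as a hypothesis. Reads shared between hox paralogs were not tested.

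The genes *shha*, *foxd3* and *sox2* were higher in spt_cMO, the first pair from low levels. Whether more notochord cells raised *shha* and *foxd3* cannot be told from the list. The other 14 tested genes of the notochord list had a median log2 fold change of 0.090, with 9 higher and 5 lower, against 1.84 for this pair. The SE of 0.12 came from resampling genes, not libraries, and so leaves out the spread between libraries. The pair was picked after its values were seen, and genes that the progenitors also express would rise less. The list's mean per library was 0.21 higher (exact permutation p = 0.468). Of that list *tbxta* was the most abundant, at 439 CPM in spt_cMO, and 6 of its 16 tested genes also stand in another list. Nor can it be told whether more neural cells raised *sox2*. The other 28 tested neural genes had a median of 0.12 (SE 0.05, again over genes), with 19 higher and 9 lower, against 0.83 for *sox2*. As *sox2* was picked as the only called gene of that list, a lower median of the rest was likely from the choice alone. The list's mean per library was 0.11 higher (exact permutation p = 0.444). Of its 29 tested genes 7 also stand in another list. The most abundant, *her9* and *sox11b*, both named outside the rule, were at 580 and 540 CPM in spt_cMO. A gain of neural cells, a change of *sox2* within the cells, or both stay open, as does the morpholino itself. How many genes of either list the progenitors themselves express cannot be read from these libraries.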

How the results depend on the processing

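The 6 called lists kept the call in 35 and lost it in 25 tests that used all libraries, and kept it in 70 and lost it in 20 with libraries left out. For the 57 named genes, alternatives that used all libraries gave 593 values on the same side, 11 that lost and 10 that gained the call, and none reversed; leaving libraries out gave 722, 129 and 4. The 11 were *fzd10*, *fgf24* and *tbxta* after thinning, *arl4aa* and *tbxta* without a filter, *ccnd1* and *osr1* with upper quartile scaling, *ccnd1* and *hoxd10a* without robust estimation, and *her1* with RLE and at a mean of 20 CPM. Of 51 called named genes, 39 kept the call without each single library and 12 lost it without at least 1 (adjusted p 0.0517 to 0.148). Those fits had no block. With the replicate block and all libraries the 12 all passed, with adjusted p from 0.000936 for *lft1* to 0.0222 for *tbxta*. Leaving out a single library was not combined with the block. Thinning was planned for records detected and the share of the 10 most counted records, and elsewhere was chosen after seeing the data. Also chosen after seeing the data were the authors' model, the estimated correlation with the block, the exact permutation of list means (also after thinning) and the hox classes on the same genes. The cause of a change was not tested except where named.

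The 53 higher and 64 lower records became 34 and 40 with a filter at a mean of 20 CPM, where fewer records are tested, 26 and 39 at an adjusted p under 0.01, which is stricter, and 126 and 121 in the authors' model. The higher records were 88 with the replicate block and 83 with DESeq2. Leaving out libraries or numbers gave 31 to 56 higher and 42 to 70 lower, with fewer libraries in each fit. Another scaling moved the median of all genes by at most 0.02.

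*tbx16* passed at 0.43 without a filter (adjusted p = 0.0414), at 0.43 with the replicate block (0.0172), at 0.45 in the exact test (0.0495) and at 0.44 in the authors' model (0.0027), and ranged from 0.36 to 0.54 with libraries left out. The 6 lists became 3 after thinning, which ended the calls of Notch, germ cells (both 0.0743) and adhesion (0.183) at differences of 0.15, -0.32 and -0.11 (Notch and adhesion still passed the exact permutation after thinning, adjusted p = 0.0437 each), 0 with an estimated correlation, 0 with that and the block, and 3 to 7 with libraries left out.

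Hox groups 1 to 4 missed the threshold without a filter (0.19) and in the replicate block, where 5 pairs cannot pass (0.28), as groups 9 to 13 did there (0.56). Groups 5 to 8 passed without a filter (0.33). With libraries left out and the filter run again, which changed the genes, the ranges were 0.24 to 0.35, 0.15 to 0.35 for groups 5 to 8 and 0.55 to 0.71 for groups 9 to 13. On the same genes they were 0.24 to 0.33, 0.12 to 0.26 and 0.47 to 0.63, and after thinning groups 1 to 4 missed the threshold (0.27). The difference in records detected turned to 80.6 after thinning to equal depth. That in the share of the 10 most counted records ranged from -0.05 to 0.39 with libraries left out, reversing at -0.011 and -0.0502 without control replicates 2 and 3, that in totals from -2717334 to -776556 counts and that in records detected from -686 to -180. Of the named genes and the lists, the block also changed the calls of *klf2a* and the neural list. The 2 planned tests on the authors' normalized values per library were not run, because that table holds none. At the smallest total of 2036973 counts 3 reads are 1.47 CPM.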

Other observations

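The numbers of calls were compared with those of other splits of the 10 libraries into groups of 5. Of 126 such splits 100 were drawn, and only the real one gave as many genes: 117, against 8 for the highest other. If same-numbered libraries are not pairs, chance can be excluded for the number of genes at the 0.05 level (1 of 100). Of the 16 splits that part all 5 same-numbered pairs the real one gave 117 genes and the highest other 2, or 181 and 7 with the block; 16 splits are too few for a share under 0.05. For the number of lists chance cannot be excluded, since 10 of the 100 splits gave at least 6 lists and the highest other gave 9. The list calls therefore cannot rest on their number, only on the single lists and their values per library. Even there, the adjusted p of 0.0437 in the exact permutation depended on 4 lists tying at the smallest possible p, 0.00794. Fewer lists at that p would have raised it. The 4 lists are not independent either, since *her1*, *lfng* and *pcdh8* each stand in more than 1 of them.

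Few genes of the growth and stress lists passed. Of 80 tested genes of the ribosomal protein list, whose name rule also took in 3 S6 kinase genes, none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.542); *rpl11*, with the smallest p, was at 894 CPM ± 92.9 in control and 1099 CPM ± 176 in spt_cMO (adjusted p = 0.339). Of 15 p53 response genes none passed over all genes and 1 was lower adjusted over the list alone (camera adjusted p = 0.542); *plk3*, a polo-like kinase, was at 102 CPM ± 10.4 and 75.1 CPM ± 13.8 (adjusted p = 0.0863). Activation of p53 is a known side effect of some morpholinos, and the list's median log2 fold change was -0.02. *plk3* passed without a filter on low counts (adjusted p = 0.0286), in DESeq2 (0.0428) and in the authors' model (0.049), lower in each.

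Of 35 cell cycle genes *ube2c*, which encodes an enzyme of mitotic exit, fell from 942 CPM ± 193 to 639 CPM ± 86.5, and the cyclin gene *ccnd1* from 2766 CPM ± 486 to 2000 CPM ± 172; adjusted over the list alone the same 2 were lower. The list did not pass (camera adjusted p = 0.929, direction up), with a median of 0.01 and a mean of -0.01. Both calls were lost without single libraries, with adjusted p up to 0.11 without spt_cMO replicate 4 and 0.108 without control replicate 4. Of the yolk syncytial layer list 2 genes were tested and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.287); *gata6* was at 54.4 CPM ± 11.3 and 46.1 CPM ± 4.73 (adjusted p = 0.664).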
